A study of Mus musculus with 20 samples.

How the data were processed

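Gene expression was measured in the left ventricle of mice that had undergone myocardial infarction, at 4 time points: days 3, 5, 7 and 14. RNA from the non-infarcted part of the ventricle of infarcted hearts was hybridised on each array together with RNA from the left ventricle of sham-operated mice, per the labels. The series holds 20 arrays, 5 for each time point, from 4 male mice per group with 1 dye swap at each time point, per the series' design text. Which array is the swap, whether RNA was pooled, and whether sham animals were shared between arrays or days is not given in the sources used here. The p-values therefore measure the spread between arrays, and they are too small where 2 arrays share animals. RNA was isolated with a Promega silica-membrane kit and labelled with an Agilent linear amplification kit for low RNA input, with channel 1 in Cy5 and channel 2 in Cy3, per the labels' protocols. No scanner files, intensities or background values were used here, so no probe could be judged against background. The number of arrays limits the precision of every value.

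The values are log ratios as the authors deposited them, 22575 spots on each of 20 arrays, with 0 missing values and 0 values equal to 0. The authors' background correction, normalisation, log base and ratio direction are not given in the sources used here. The deposited values were read as log2 ratios: the largest absolute value was 4.87, which in base 10 would be a ratio of 74131, above the top value of 65535 of a 16-bit scanner. The natural logarithm could not be excluded, in which case every fold given here is too small. The deposited columns had medians near 0. Those of arrays 1 to 5 were -0.000842, -0.0218, 0.0101, -0.0337 and -0.0172 at day 3, and -0.0116, -0.00534, -0.0234, -0.0108 and -0.052 at day 5. They were 0.0034, 0.0105, -0.00883, 0.0349 and 0.0159 at day 7, and -0.00187, 0.0118, -0.00105, 0.00625 and 0.0192 at day 14. Whether the authors centred the arrays is unknown; here the median of each array was subtracted.

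The direction of the ratio was read from the arrays. A preset rule set pairs of arrays of one day with opposite dyes against pairs with like dyes, by Pearson's r over all spots. Among all 20 arrays, opposite-dye pairs had a mean r of 0.101 over 22 pairs and like-dye pairs 0.205 over 18 pairs. Among the 17 arrays kept, the opposite-dye mean was 0.264, with 1 of 17 pairs below 0, and the like-dye mean was 0.541. A mean above 0 for opposite dyes goes with columns turned to one order of the 2 RNAs, but the rule also asked for values not clearly below those of like dyes, and this was not met. The correlations cannot tell which RNA comes first: sham over infarct fits them equally well and would turn each sign. The basis for infarct over sham is a check fixed in advance on the collagens and the stress genes, whose means over the 4 days were 0.85 and 0.77 in that order. That check takes a rise of these lists after infarction from outside the data, so their own direction is assumed here and not found. The direction is therefore called likely and not settled, and values for the ratios read as not turned stand in the closing section.

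Day 5 array 4 and day 7 arrays 4 and 5 had a negative correlation with each of the other 17 arrays, under -0.3 with 12, 14 and 13 of them, including arrays of their own day and dye orientation. Their direction is not settled, and they were left out of the fit. This departs from the design, which had fixed a fit of all 20 arrays, and it was decided after the data had been seen. Because those arrays were set aside for their values, the p-values of the remaining arrays are too small to an unknown degree, most of all at days 5 and 7 and on the mean. The number of genes past the threshold in each comparison, and of list calls, is given a further 3 times; counts within lists, shared between days or beyond 2-fold are given for the 17 arrays alone. The 3 further fits are those of all 20 arrays as deposited, which is the fit as designed, and of all 20 arrays with those 3 turned, with their dyes as labelled or exchanged. No other array was left out or turned. The fit held 5 arrays at day 3, 4 at day 5, 3 at day 7 and 5 at day 14.

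Spots were named through the platform annotation, and symbols were checked through Entrez gene identifiers against a RefSeq gene table, which changed 0 symbols. The numbering of the annotation did not follow the order of the deposited values. The order was found from the data, after they had been seen, among 8 ways to number a layout of 215 lines of 105 spots. Under the numbering used, with lines and columns exchanged and both counted from the other end, probes of one accession had a mean r of 0.462 over 896 pairs. The 7 other numberings gave -0.00641 to 0.0234. As a test outside that choice, probes of one gene with different accessions had a mean r of 0.0745 over 836 pairs, a low value, against -0.0179 to 0.0331 in the other numberings. The mean r between genes of one preset list was 0.233, against -0.00126 to 0.0102. A gene name thus rests on this numbering. Of the spots, 18218 had 1 gene symbol, 16 had several and 4341 had none here; the last 2 kinds are unnamed in this text. The Entrez gene of 18175 probes was in the RefSeq table, and the other 43 probes keep the annotation's symbol. Probes of a gene were averaged, which gave 16504 genes, 1193 of them with more than 1 probe.

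Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with a coefficient for each of the 4 days and a dye term for each gene, since the dye orientations are unequal in number at every day. The fit left 12 residual degrees of freedom, and the prior had 5.50. Each day was tested against 0, as were the mean of the 4 days, the differences between days and an F test of equality of the 4 days. All tests were two-sided, with Benjamini-Hochberg adjustment over the 16504 genes and a threshold of 0.05 on the adjusted p. Errors of log2 changes are standard errors from this fit. "Adjusted over the list alone" means adjustment over the members of the list. Gene lists were tested with camera at its preset correlation of 0.01, with adjustment over 30 lists at the 4 days and on their mean, 150 tests. Camera with an estimated correlation and fry are given beside it. The lists had 750 preset entries, of which 679 were measured. No test of lists between days had been fixed; camera and fry were both run for these, and fry was taken as the test after their counts had been seen.

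The design, the gene lists, the rule for naming genes and the alternatives not marked otherwise were chosen before the data were examined. For each day and for the mean, the naming rule takes the 10 genes with the largest change in each direction among those past the threshold with one sign on all arrays of the day, or at all 4 days for the mean. It adds the 4 members of each list with the smallest p, the 5 largest in each direction for each difference between days, and always Nppa, Nppb, Myh6, Myh7, Acta1, Col1a1, Col3a1, Timp1 and Postn. Which of the list members are printed was chosen after their values were seen.

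The alternatives were no dye term, no centring, scaling of the arrays to a common spread, averaging of a guessed swap pair at each day, each probe alone, a robust prior, array weights, separate fits per comparison, the ratios read as not turned, the array number as a block, and each array left out in turn. The 3 readings of all 20 arrays were added after the data had been seen. The fit was tested on simulated data with the real array design. For 100 genes shifted by a log2 change of 1, it recovered 100% at day 3, 97% at day 5, 99% at day 7 and 99% at day 14. At a shift of 0.5 it recovered 98%, 97%, 92% and 98% at these days, and with no change simulated it made 0 calls at the 4 days and their mean. The runs with shifted genes also made 7, 9, 10 and 7 false calls at these days. The simulated noise was independent between genes and between arrays, with the spread taken from the fit itself. It held no shared animals and no choice among arrays, so it cannot judge the effect of either. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15.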

Results

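The study followed gene expression in the surviving left ventricle of infarcted mouse hearts. On each array, RNA of non-infarcted tissue of an infarcted heart competed with RNA of a sham-operated left ventricle, so every ratio is read against the surgical control. After 3 arrays without a settled direction were set aside, 5 arrays remained at day 3, 4 at day 5, 3 at day 7 and 5 at day 14, and 16504 genes were tested. Positive log2 changes stand for higher expression after infarction, which is the likely direction of the deposited ratios but not settled. Were the ratios sham over infarct, each sign below would turn, with sizes and counts unchanged. Were they dye ratios that the authors had not turned, 220 of the 276 gene values named here would change sign, 16 of them past the threshold. In that reading no list call at the days or on their mean is kept in its direction: of the 77 calls in camera at the preset correlation, 64 list means change sign, 23 of them past the threshold. So each rank and each direction below, of genes and of lists, rests on the reading used. The preset rule tied unturned dye ratios to a mean r below 0 between arrays of opposite dyes. That mean was 0.101 over all 20 arrays, and 0.279 and 0.104 at days 3 and 14, which lost no array. With the opposed arrays included, it was 0.180 at day 5 and -0.130 at day 7. Like-dye pairs of day 7 had a mean of -0.230, so that day does not separate the readings. Apart from day 7, these values argue against unturned ratios, although the rule's condition for turned ratios was not met in full. On every array of days 3 and 14, under both dye orientations, the centred ratios of Nppa, Postn and Myh7 were above 0. Those of Nppa ran from 2.16 to 3.19 at day 3 and from 1.42 to 3.54 at day 14. Unturned ratios would make this shared sign an effect of the dye.

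The first comparison asked which genes differed between infarct and sham with the 4 days averaged, which does not ask for a change at every day. On the mean of the 4 days, Nppa, which encodes atrial natriuretic peptide, was higher by a log2 change of 2.95 ± 0.10 (SE, 17 arrays, adjusted p = 2.79e-12). Postn, the matricellular protein periostin, was higher by 2.72 ± 0.11, and Myh7, the beta myosin heavy chain of the fetal heart, by 2.69 ± 0.17. Col8a1 (2.23 ± 0.07), the growth factor-like matrix protein Ccn2 (2.09 ± 0.13), the nicotinamide riboside kinase Nmrk2 (1.84 ± 0.08), Nppb (1.78 ± 0.11), which encodes brain natriuretic peptide, Fstl1 (1.78 ± 0.07), Ltbp2 (1.75 ± 0.09) and Ankrd1 (1.67 ± 0.11) were also among the 10 largest. The largest decreases were in Hrc, the histidine-rich calcium-binding protein of the sarcoplasmic reticulum, which fell by 1.11 ± 0.07 (adjusted p = 1.17e-09), and in Ift81, which fell by 1.07 ± 0.09. Rbfox1 (-1.0 ± 0.07), a splicing factor, Dbp (-0.92 ± 0.19), Ano10 (-0.92 ± 0.06), the carboxylesterase Ces1d (-0.86 ± 0.07), Lrtm1 (-0.84 ± 0.09), the mitochondrial kinase Pink1 (-0.82 ± 0.05), Cmya5 (-0.82 ± 0.06) and Ech1 (-0.82 ± 0.04), an enzyme of fatty acid oxidation, completed the 10 lowest. In all, 4821 genes passed the threshold in limma, 2726 higher and 2095 lower. Of these, 2230 of the higher and 1737 of the lower genes had one sign at all 4 days. A 2-fold change was exceeded by 43 of the higher and 2 of the lower genes. The fit as designed, with all 20 arrays as deposited, called 0 genes in limma on this mean, with 3293 at an unadjusted p under 0.05. With the 3 opposed arrays turned it called 5082 (dyes as labelled) or 6089 (dyes exchanged).

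Lists of extracellular matrix genes were tested at each day. Among 16 measured collagens, 13 were higher at day 3, 15 at day 5, 14 at day 7 and 13 at day 14, and 0 were lower; adjusted over the list alone, 14, 16, 15 and 14 were higher. Their mean log2 change was 0.68, 1.05, 1.01 and 0.68 at these days, and the shift passed camera at each day, with adjusted p = 0.0382, 0.0108, 0.0108 and 0.00982 with an estimated correlation. Read as not turned, the collagen means were -0.16, -0.30, -0.36 and -0.16, and those of the matrix glycoproteins -0.15, -0.23, -0.33 and -0.16. On the mean of the days, Col3a1 was higher by 1.35 ± 0.11 and Col1a1 by 1.14 ± 0.09, both fibrillar collagens. Of 33 matrix glycoproteins and matricellular proteins, 19, 26, 24 and 16 were higher at days 3, 5, 7 and 14, and 1 was lower at day 3. Adjusted over the list alone, 22, 26, 28 and 23 were higher and 2 lower at day 3. Their mean changes were 0.55, 0.86, 0.98 and 0.60; the estimated correlation left adjusted p = 0.0553 at day 3, which misses the threshold, and 0.0108, 0.0108 and 0.00982 later. The 27 matrix proteases and inhibitors had mean changes of 0.24, 0.35, 0.29 and 0.16 and passed at the preset correlation, but with an estimated correlation their adjusted p was 0.231, 0.105, 0.142 and 0.0889. Timp1, an inhibitor of these proteases, was higher by 0.71 ± 0.08 on the mean of the days. Markers of fibroblasts and myofibroblasts moved with these groups. Of 17 markers 8, 11, 13 and 7 were higher at the 4 days and 3, 1, 1 and 0 lower (10, 13, 14 and 12 higher and 3, 1, 1 and 0 lower adjusted over the list alone), with mean changes of 0.39, 0.62, 0.62 and 0.46. The estimated correlation gave adjusted p = 0.12 at day 3, then 0.0164, 0.0108 and 0.00982. Postn, Lum and Dcn are members of both the matricellular and the fibroblast list, and Mmp2 of both the protease and the fibroblast list.

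Lists of cardiomyocyte genes were examined next. Of 19 stress and fetal cardiomyocyte genes, 10, 9, 10 and 8 were higher at days 3, 5, 7 and 14, and 1 was lower at day 3; adjusted over the list alone, 10, 9, 11 and 9 were higher and 2 lower at day 3. The list's mean changes were 0.60, 0.83, 0.98 and 0.66, and with an estimated correlation its adjusted p was 0.0554, 0.0235, 0.0108 and 0.0108. Read as not turned, the means were 0.057, -0.076, -0.18 and -0.12. Acta1, the skeletal alpha-actin re-expressed in stressed myocardium, was higher by 0.97 ± 0.07 on the mean of the days. Myh6, the adult alpha myosin heavy chain, was lower by this mean at -0.50 ± 0.08 (adjusted p = 7.94e-05). As a list, the 22 adult contractile genes passed only at day 5, with a mean of -0.14 and 4 members lower, or 5 adjusted over the list alone, and adjusted p = 0.055 with an estimated correlation. Its camera adjusted p was 0.56, 0.597 and 0.796 at days 3, 7 and 14. There 3, 2 and 0 members were higher and 6, 5 and 1 lower. Adjusted over the list alone, these were 5, 2 and 0 higher and 7, 6 and 1 lower. The 28 ion channel and calcium handling genes passed at day 14 only, with a mean of -0.06, 3 members lower (3 adjusted over the list alone) and adjusted p = 0.178 with an estimated correlation. The adjusted p of that list was 0.0675, 0.168 and 0.187 at the 3 earlier days. There 3, 3 and 2 members were higher and 6, 4 and 2 lower. Adjusted over the list alone, these were 3, 3 and 2 higher and 6, 4 and 3 lower.

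Mitochondrial energy metabolism was covered by 2 lists. Of 30 fatty acid oxidation genes, 20, 21, 19 and 14 were lower at days 3, 5, 7 and 14, with 0 higher; adjusted over the list alone, 21, 23, 21 and 21 were lower, and 1 was higher at days 7 and 14. Their mean changes were -0.39, -0.44, -0.45 and -0.29, with adjusted p = 0.0357, 0.02, 0.0273 and 0.0162 with an estimated correlation. Of 49 genes of the TCA cycle and oxidative phosphorylation, 30, 31, 39 and 16 were lower, and 33, 39, 44 and 33 adjusted over the list alone, with 1 higher at day 3. The mean changes of this list were -0.26, -0.31, -0.45 and -0.26, with adjusted p = 0.0511, 0.024, 0.0108 and 0.0108 with an estimated correlation, so the day 3 call is lost there. Read as not turned, the means were 0.0031, -0.06, 0.023 and -0.066 for fatty acid oxidation and -0.078, -0.02, 0.038 and -0.032 for the other list, and neither passed camera at any day. The 23 genes of glucose uptake and glycolysis did not shift as a list at any day (camera adjusted p = 0.766, 0.761, 0.978 and 0.791), with members on both sides. On the mean of the days the phosphofructokinase Pfkp was higher at 0.51 ± 0.04, while the lactate dehydrogenase subunit Ldhb (-0.52 ± 0.04) and the insulin-responsive glucose transporter Slc2a4 (-0.53 ± 0.05) were lower.

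Markers of blood-borne cells were less uniform. Of 27 macrophage and monocyte markers 20 were higher at day 3, 16 at day 5, 12 at day 7 and 0 at day 14, with mean changes of 0.46, 0.53, 0.43 and 0.10; adjusted over the list alone, 21, 18, 18 and 2 were higher. The list passed camera at each day, but the estimated correlation was high and gave adjusted p = 0.122, 0.113, 0.142 and 0.456. Read as not turned, the means were -0.16, -0.17, -0.15 and -0.18. The 12 neutrophil markers did not pass at any day (camera adjusted p = 0.348, 0.732, 0.761 and 0.739), and S100a8 at -0.25 ± 0.18 and S100a9 at -0.48 ± 0.31 did not pass on the mean of the days. The 19 lymphocyte markers (adjusted p = 0.262, 0.504, 0.56 and 0.767), the 10 class II MHC genes (0.761, 0.577, 0.0549 and 0.954) and the 6 red cell markers (0.278, 0.732, 0.176 and 0.313) did not pass camera either. Single members did on the mean of the days, among them the B-cell adaptor Blnk at 0.40 ± 0.04 and H2-DMb1 at 0.22 ± 0.05.

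At day 3, 3369 genes passed in limma (5 arrays), 2076 higher and 1293 lower, 55 and 7 of them beyond 2-fold. The largest increases were in Postn (2.95 ± 0.20), Nppa (2.80 ± 0.19), Col8a1 (2.07 ± 0.13), Nmrk2 (2.05 ± 0.14), Ccn2 (1.93 ± 0.23), Fstl1 (1.73 ± 0.13), the alpha-tubulin Tuba1a (1.58 ± 0.10), Myh7 (1.58 ± 0.30), Anxa2 (1.55 ± 0.14) and the monocyte chemokine Ccl2 (1.51 ± 0.22, adjusted p = 9.57e-05). Decreases were led by Ano10 (-1.28 ± 0.10), the actin-severing protein Gsn (-1.14 ± 0.10), Cmya5 (-1.13 ± 0.10), Pink1 (-1.05 ± 0.09), Nr4a1 (-1.03 ± 0.33), Hrc (-1.03 ± 0.12), Lrtm1 (-1.01 ± 0.16), Clec3b (-0.99 ± 0.13), Ift81 (-0.96 ± 0.16) and the glutathione transferase Gstm1 (-0.94 ± 0.07). Nr4a1 had an adjusted p of 0.0361, and lost the call without array 1 (0.0956) or array 2 (0.21). Nppb was higher by 1.45 ± 0.19, Acta1 by 0.69 ± 0.13, Col1a1 by 0.91 ± 0.15, Col3a1 by 0.85 ± 0.20 and Timp1 by 0.74 ± 0.14, while Myh6 was at -0.62 ± 0.14 (adjusted p = 0.00395). Without array 2, 1744 genes passed. All 20 arrays as deposited gave 1332 genes, and the 3 turned arrays 2757 or 3556 with dyes as labelled or exchanged.

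Cell division and ribosomal protein genes were among the groups higher at day 3. Of 38 cell cycle genes 29 were higher and 0 lower, with a mean change of 0.41 and adjusted p = 0.037 with an estimated correlation; 30 were higher adjusted over the list alone. Among them were the proliferation antigen Mki67 (1.25 ± 0.14), the replication clamp Pcna (0.59 ± 0.05) and the G1 cyclin Ccnd1 (0.95 ± 0.08). Of 28 ribosomal protein genes 26 were higher, with a mean of 0.47 and adjusted p = 0.0108 with an estimated correlation, and 27 were higher adjusted over the list alone; Rpl3 was at 1.28 ± 0.12, Rplp1 at 0.87 ± 0.08 and Rpl12 at 0.74 ± 0.06. With the table read as not turned, the cell cycle mean at day 3 was -0.13 and the ribosomal one -0.19. The interferon response list (20 genes, 6 higher and 1 lower, or 9 and 1 adjusted over the list alone) had a mean of 0.22, and its call was lost with an estimated correlation (adjusted p = 0.212); Isg15 was higher by 0.68 ± 0.08 and Bst2 by 0.85 ± 0.10. The 31 genes of heat shock, hypoxia and oxidative stress had a mean of 0.15 with 12 higher, or 12 higher and 3 lower adjusted over the list alone, among them the haem oxygenase Hmox1 (0.85 ± 0.10), and adjusted p = 0.259 with an estimated correlation. That list did not pass at days 5, 7 and 14 (0.767, 0.761 and 0.761).

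Further members of the lists at day 3 were the collagen chain Col1a2 (1.31 ± 0.13), its chaperone Serpinh1 (1.31 ± 0.11), the membrane metalloprotease Mmp14 (1.29 ± 0.18), the cathepsin Ctss (1.27 ± 0.18) and the filament protein Vim (1.45 ± 0.10). The macrophage markers Lgals3 and Trem2 were higher by 1.13 ± 0.09 and 1.12 ± 0.12, and the stress list members Uck2 and Fhl1 by 1.44 ± 0.11 and 1.12 ± 0.11. Tnfrsf12a, a receptor of the TNF family, was higher by 1.38 ± 0.12, although its list of 48 chemokines, cytokines and receptors did not pass at that day (adjusted p = 0.174). S100a9 was at -0.86 ± 0.56 (adjusted p = 0.314). On the lower side stood the calcium pump Atp2a2 (-0.86 ± 0.11) and its regulator Pln (-0.51 ± 0.11), while Sri, another calcium handling gene, was higher by 0.63 ± 0.08. Ech1 (-0.79 ± 0.08), Etfb (-0.79 ± 0.09), Ndufv1 (-0.69 ± 0.05), Cox8b (-0.75 ± 0.09), Ldhb (-0.73 ± 0.07) and the muscle creatine kinase Ckm (-0.61 ± 0.11) were lower. The glycolytic Pgk1 (0.38 ± 0.05), the mesothelial and epithelial keratin Krt18 (0.49 ± 0.04) and desmin, Des (0.71 ± 0.12), were higher, the last without a call when the dye term was left out (adjusted p = 0.065). Timp1 lost its call in a fit of the day 3 arrays alone (0.0651).

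At day 5, 2245 genes passed in limma (4 arrays), 1555 higher and 690 lower, 90 and 11 of them beyond 2-fold. Postn (3.17 ± 0.23), Nppa (2.81 ± 0.21), Myh7 (2.41 ± 0.34), Col8a1 (2.39 ± 0.14), Ccn2 (2.26 ± 0.26), Nmrk2 (2.14 ± 0.16), Ltbp2 (2.08 ± 0.18), Nppb (2.02 ± 0.22), the thrombospondin Thbs4 (2.02 ± 0.14) and Fstl1 (1.96 ± 0.15) were the highest. The lowest were the clock output gene Dbp (-1.74 ± 0.38), Hrc (-1.39 ± 0.14), the endoplasmic reticulum stress gene Herpud1 (-1.23 ± 0.20), Gsn (-1.20 ± 0.12), Ces1d (-1.15 ± 0.14), Shld1 (-1.10 ± 0.15), Ano10 (-1.08 ± 0.12), Gpcpd1 (-1.05 ± 0.14), Rbfox1 (-1.02 ± 0.14) and the clock gene Per2 (-1.02 ± 0.23). Col3a1 was higher by 1.65 ± 0.23, Col1a1 by 1.37 ± 0.18, Acta1 by 0.79 ± 0.14 and Timp1 by 0.74 ± 0.17, and Myh6 was at -0.67 ± 0.16 (adjusted p = 0.00789). Without array 1, 1165 genes passed, and Timp1 (adjusted p = 0.0548), Myh6 (0.0679), Dbp (0.0661) and Per2 (0.131) were not called. That array alone held infarct RNA in Cy5 at day 5, so without it the day leans on the dye term of the other days. Myh6 was not called without array 3 either (0.064). All 20 arrays as deposited gave 0 genes in limma, with 1395 at an unadjusted p under 0.05, and the turned arrays 1995 or 2827 with dyes as labelled or exchanged.

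Cell cycle genes were still higher at day 5, with 32 of 38 called, a mean of 0.45 and adjusted p = 0.0273 with an estimated correlation; 33 were called adjusted over the list alone. The mitotic genes Ccnb2 and Cdc20 were higher by 1.04 ± 0.09 and 1.00 ± 0.11. Of 28 ribosomal protein genes 16 were higher, or 24 adjusted over the list alone, with a mean of 0.33 and adjusted p = 0.034 with an estimated correlation; Rpl6 was at 0.51 ± 0.06. Macrophage markers included Trem2 (1.39 ± 0.13), Ms4a7 (1.01 ± 0.11), Mpeg1 (1.01 ± 0.11) and Adgre1 (0.83 ± 0.09), which encodes F4/80. Of 16 complement genes 5 were higher, also 5 adjusted over the list alone, with a mean of 0.19 and adjusted p = 0.341 with an estimated correlation, among them C1qa (1.01 ± 0.18) and C1qb (0.52 ± 0.07). Complement did not pass at day 3 (adjusted p = 0.403) or day 14 (0.106). The interferon list had a mean of 0.21 with adjusted p = 0.163 with an estimated correlation, and the chemokine and cytokine list one of 0.16, with 9 higher and 2 lower (14 and 2 adjusted over the list alone) and adjusted p = 0.341 in the same test; Osmr, the oncostatin M receptor, was higher by 0.75 ± 0.12.

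Further lists at day 5 passed camera at the preset correlation but not with an estimated one. Of 28 genes of TGF-beta and BMP signalling 6 were higher, or 9 adjusted over the list alone, with a mean of 0.15 and adjusted p = 0.118 with an estimated correlation, including the ligand Tgfb3 (0.99 ± 0.08) and the receptor Tgfbr2 (0.67 ± 0.12). Of 25 Wnt pathway genes 6 were higher, also 6 adjusted over the list alone, with a mean of 0.20 and adjusted p = 0.163 with an estimated correlation; Sfrp1 (1.08 ± 0.11) and Frzb (0.71 ± 0.09) encode secreted antagonists of Wnt ligands. Of 15 clock genes 5 were lower and 1 higher (6 and 2 adjusted over the list alone), with a mean of -0.23 and adjusted p = 0.102 with an estimated correlation; Hlf (-0.52 ± 0.08) and Nr1d2 (-0.32 ± 0.06) were lower and Arntl (0.58 ± 0.10) higher. Arntl lost its call with all 20 arrays, the 3 turned and dyes as labelled (adjusted p = 0.0598). The clock list did not pass at days 3, 7 and 14 (camera adjusted p = 0.261, 0.767 and 0.47). Loxl1 (1.16 ± 0.07), Ctss (1.89 ± 0.21), Mmp14 (1.76 ± 0.20), Meox1 (1.39 ± 0.09), Cilp (1.70 ± 0.14), Krt18 (0.95 ± 0.05) and Nppc (0.86 ± 0.13), C-type natriuretic peptide, were higher. Ech1 (-0.87 ± 0.09), Eci1 (-0.75 ± 0.08), Sdha (-0.63 ± 0.11), Cox7a1 (-0.53 ± 0.09), Ckm (-0.74 ± 0.12), Tnni3 (-0.57 ± 0.10), Atp2a2 (-0.62 ± 0.12) and Pln (-0.58 ± 0.13) were lower.

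At day 7, 1585 genes passed in limma (3 arrays), 901 higher and 684 lower, 70 and 6 of them beyond 2-fold. Myh7 led with 3.69 ± 0.38 (adjusted p = 7.87e-06), followed by Nppa (3.28 ± 0.24), Col8a1 (2.62 ± 0.16), Postn (2.62 ± 0.26), Ltbp2 (2.46 ± 0.20), Ccn2 (2.42 ± 0.30), the secreted chaperone Clu (2.36 ± 0.19), Ankrd1 (2.32 ± 0.25), Nmrk2 (2.18 ± 0.18) and Nppb (2.18 ± 0.25). Ift81 (-1.45 ± 0.21), Rbfox1 (-1.28 ± 0.16), Hrc (-1.23 ± 0.16), the noncoding RNA Mhrt of the myosin locus (-1.14 ± 0.22), Ces1d (-1.12 ± 0.16), Lrtm1 (-1.05 ± 0.21), Rgcc (-1.0 ± 0.19), Etfa (-0.97 ± 0.14), Acot1 (-0.96 ± 0.28) and 1810014B01Rik (-0.96 ± 0.09) were the lowest. Col3a1 (1.60 ± 0.26), Col1a1 (1.31 ± 0.20), Acta1 (1.14 ± 0.16) and Timp1 (0.95 ± 0.19) were higher, and Myh6 at -0.33 ± 0.18 was not called (adjusted p = 0.284). Without array 2, 760 genes passed, and without array 3, 969. Several calls of single genes ended with 1 array left out, among them Acot1 without array 1, 2 or 3 (adjusted p = 0.102, 0.219 and 0.122). Mhrt and Lrtm1 lost theirs without array 1 (0.0791 and 0.0818), and Rgcc without array 2 (0.0654). Among the kept day 7 arrays, array 1 alone held infarct RNA in Cy5, so without it the day leans on the dye term of the other days.

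This day rests most on the arrays set aside. All 20 arrays as deposited gave 0 genes at day 7 in limma, with 232 at an unadjusted p under 0.05, and the turned arrays 3329 or 4076 with dyes as labelled or exchanged. In these 3 fits Myh7 was at 0.43, 4.00 and 4.00, Nppa at 0.47, 3.49 and 3.48, and Postn at -0.06, 3.23 and 3.22.

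Cell cycle genes were at a mean of 0.12 at day 7, with 4 of 38 higher, or 5 adjusted over the list alone, and adjusted p = 0.417 with an estimated correlation. Top2a (0.35 ± 0.10) and Kif22 (0.38 ± 0.09) were among these, without a call when array 2 (adjusted p = 0.119 and 0.126) or array 3 (0.19 and 0.107) was left out. Ribosomal protein genes had a mean of 0.19 with 6 of 28 higher, or 9 adjusted over the list alone, and adjusted p = 0.156 with an estimated correlation. The 18 genes of the renin-angiotensin, endothelin and natriuretic peptide system passed with a mean of 0.40, a median of 0.08 and 3 members higher, which were Nppa, Nppb and Nppc (1.18 ± 0.15); the estimated correlation gave adjusted p = 0.0514. At days 3 and 5 that list had camera adjusted p = 0.57 and 0.616. Nppa and Nppb are also members of the stress and fetal cardiomyocyte list. TGF-beta and BMP signalling had a mean of 0.16, with 5 of 28 higher (7 adjusted over the list alone) and adjusted p = 0.0371 with an estimated correlation, and Tgfb3 at 1.03 ± 0.09. The Wnt pathway list had a mean of 0.24 with 6 of 25 higher, among them the secreted antagonists Sfrp1 (1.46 ± 0.13) and Sfrp2 (1.57 ± 0.18), and adjusted p = 0.138 with an estimated correlation. Endothelial markers (20 genes) had a mean of 0.12 with 3 higher and 1 lower (5 and 1 adjusted over the list alone) and adjusted p = 0.153 with an estimated correlation. The complement, interferon and chemokine lists had means of 0.18, 0.13 and 0.16 and lost their calls with an estimated correlation (adjusted p = 0.23, 0.341 and 0.323).

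Among list members at day 7, Mfap4 (1.49 ± 0.11), Meox1 (1.34 ± 0.10), Cilp (1.90 ± 0.16), Trem2 (1.33 ± 0.15), Lgals3 (1.01 ± 0.12), Gpnmb (0.83 ± 0.12), Krt18 (0.85 ± 0.05), Mybpc2 (0.93 ± 0.11), a fast skeletal myosin-binding protein, and the extracellular glutathione peroxidase Gpx3 (0.97 ± 0.10) were higher. The neutrophil protease gene Prtn3 (0.47 ± 0.09) was called, but not without array 2 (adjusted p = 0.068) or array 3 (0.0545). Ech1 (-0.91 ± 0.10), Cox7a1 (-0.78 ± 0.10), Uqcrfs1 (-0.76 ± 0.10), Tnni3 (-0.73 ± 0.12), Ckm (-0.80 ± 0.14), Pln (-0.76 ± 0.14), Atp2a2 (-0.65 ± 0.14) and the mitochondrial chaperonin Hspd1 (-0.67 ± 0.09) were lower. The call of Atp2a2 ended without array 2 (adjusted p = 0.0755).

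At day 14, 443 genes passed in limma (5 arrays), 260 higher and 183 lower, 22 and 0 of them beyond 2-fold. Myh7 (3.07 ± 0.30), Nppa (2.91 ± 0.19), Postn (2.16 ± 0.20), Col8a1 (1.86 ± 0.13), Ccn2 (1.77 ± 0.23), Fstl1 (1.5 ± 0.13), Nppb (1.48 ± 0.19), Ltbp2 (1.38 ± 0.16), Col1a2 (1.32 ± 0.13) and Col3a1 (1.29 ± 0.20) were the highest. Ift81 (-0.89 ± 0.16), Rbfox1 (-0.87 ± 0.12), Hrc (-0.80 ± 0.12), Atp2a2 (-0.73 ± 0.11), Ano10 (-0.72 ± 0.10), Ech1 (-0.72 ± 0.08), the thiolase Acaa2 (-0.68 ± 0.08), Ces1d (-0.64 ± 0.12), Aldh6a1 (-0.64 ± 0.10) and the kinase Pim3 (-0.64 ± 0.15) were the lowest. Acta1 (1.25 ± 0.13) and Col1a1 (0.98 ± 0.15) were higher, whereas Timp1 at 0.41 ± 0.14 (adjusted p = 0.188) and Myh6 at -0.38 ± 0.14 (0.206) were not called. Pim3 lost its call without array 1 (adjusted p = 0.159), 2 (0.111), 3 (0.0636) or 5 (0.062). Without array 3, 685 genes passed; without array 1, 4 or 5 there were 241, 263 and 230. All 20 arrays as deposited gave 0 genes in limma at day 14, with 711 at an unadjusted p under 0.05, and the turned arrays 282 or 415 with dyes as labelled or exchanged.

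The cell cycle list no longer passed at day 14 (mean 0.04, 0 of 38 called, camera adjusted p = 0.0515), nor did the interferon (0.241) and chemokine (0.303) lists. Macrophage markers Lgals3 (0.35 ± 0.09, adjusted p = 0.0544) and Trem2 (0.43 ± 0.12, 0.0612) fell short of the threshold. Ribosomal protein genes had a mean of 0.08 with 1 of 28 higher and adjusted p = 0.278 with an estimated correlation; that gene was Rpl3 (0.50 ± 0.12), not called without array 1 (0.175), 2 (0.131), 4 (0.0647) or 5 (0.117). TGF-beta and BMP signalling (mean 0.08) and the Wnt pathway (mean 0.15) kept adjusted p = 0.037 and 0.0371 with an estimated correlation; Tgfb3 was at 0.43 ± 0.07 and Sfrp2 at 0.94 ± 0.14. The renin-angiotensin, endothelin and natriuretic peptide list had a mean of 0.28, a median of 0.03 and adjusted p = 0.0517 with an estimated correlation, with Nppc at 0.65 ± 0.12. Endothelial and smooth muscle markers had means of 0.12 and 0.08 with 0 single genes called, and adjusted p = 0.102 and 0.122 with an estimated correlation.

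List members higher at day 14 included Mfap4 (1.16 ± 0.08), Loxl1 (0.73 ± 0.06), Cilp (1.13 ± 0.12), Meox1 (0.66 ± 0.08), Tnfrsf12a (0.81 ± 0.12), Krt18 (0.32 ± 0.04), Mybpc2 (0.49 ± 0.09) and the skeletal light chain Myl1 (0.88 ± 0.17). Myl1 lost its call without array 1 (adjusted p = 0.077). Idh3g (-0.40 ± 0.06), Cox7a1 (-0.50 ± 0.08), Pln (-0.63 ± 0.11), Hspd1 (-0.42 ± 0.07) and Tnni3 (-0.35 ± 0.09) were lower. The adjusted p of Tnni3 was 0.0429, and its call ended without any of several arrays, with the highest adjusted p, 0.288, without array 4.

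Markers of further cell types were examined for other tissue in the samples. At the 4 days, skeletal muscle markers (15 genes) had camera adjusted p = 0.761, 0.452, 0.766 and 0.548, adipocyte markers (12 genes) 0.732, 0.617, 0.104 and 0.0675, and mesothelial markers (13 genes) 0.761, 0.201, 0.56 and 0.0581. Endothelial markers at days 3 and 5 (0.133 and 0.0794) and the 14 smooth muscle and pericyte markers at days 3, 5 and 7 (0.757, 0.0515 and 0.0744) did not pass, nor did the Wnt list at day 3 (0.505), while TGF-beta and BMP signalling at day 3 had a mean of 0.12 and lost its call with an estimated correlation (adjusted p = 0.179). On the mean of the days, single markers of these types went both ways. The endothelial Icam2 (0.39 ± 0.04), the smooth muscle gene Cnn1 (0.48 ± 0.04), the pericyte receptor Pdgfrb (0.43 ± 0.05) and Mybpc2 (0.58 ± 0.05) were higher. So were Cidea (0.38 ± 0.05), Fabp4 (0.35 ± 0.06) and Krt18 (0.65 ± 0.02). Aqp1 (-0.51 ± 0.07), Kcnj8 (-0.31 ± 0.05) and the slow troponin Tnnt1 (-0.31 ± 0.05) were lower. Gpx3 (0.60 ± 0.04), a member of the oxidative stress list and no marker of these types, was also higher on this mean. Over all tests, 77 of the 150 list tests passed camera at the preset correlation, 35 with an estimated correlation and 93 with fry. All 20 arrays gave 46 gene list shifts in camera as deposited. They gave 82 or 83 with the 3 turned. With the signs of the arrays turned at random, camera at the preset correlation still gave a median of 41 calls, so its calls alone carry little weight.

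**Figure D1:**
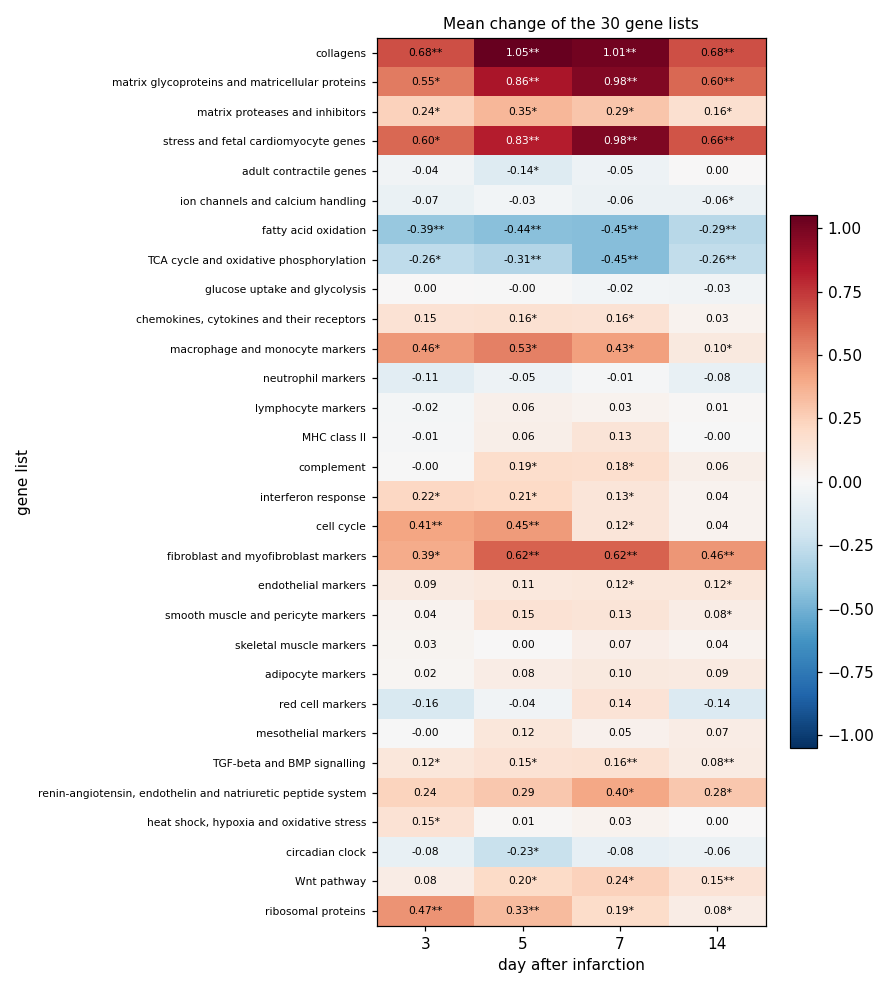
Mean log2 change (colour and number) of the measured members of each of 30 gene lists (vertical axis) by time point, days 3, 5, 7 and 14 (horizontal axis). One asterisk marks lists past an adjusted p of 0.05 in camera with its preset correlation, and a pair of asterisks those past it with an estimated correlation too; collagens range from 0.68 to 1.05, and fatty acid oxidation from -0.45 to -0.29.

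**Figure D2:**
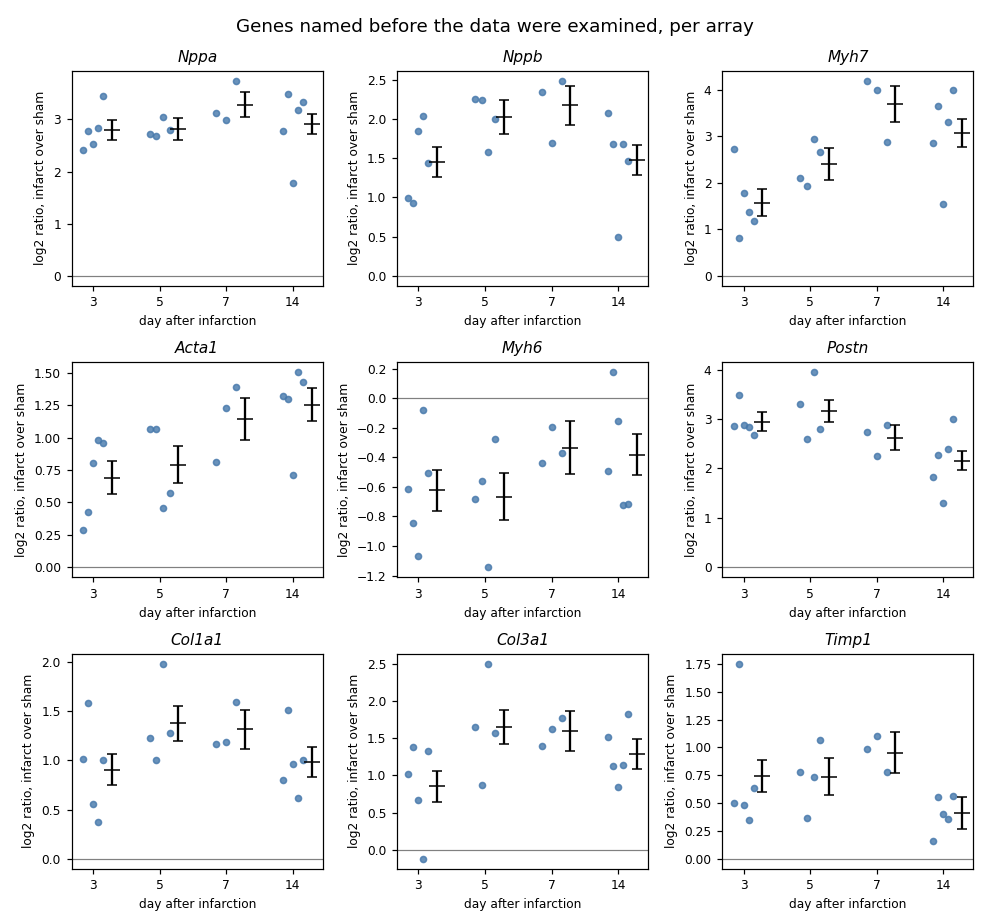
Dye-corrected log2 ratio of infarct over sham on each of the 17 arrays (points) for 9 genes, against days after infarction, with the mean of the day and its standard error from limma (bars). Myh7 means run from 1.58 at day 3 to 3.69 at day 7, and each point of Nppa, Postn, Myh7 and Acta1 lies above 0.

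The time series also asks how the response moved between days. Of 4747 genes called at 1 day or more, 190 were higher and 110 lower at all 4 days, and 15 had calls of opposite direction at different days. Days 3 and 5 shared 1061 higher and 295 lower genes, and days 7 and 14 shared 224 and 156. Independent lists of these sizes would share 196 and 54.1, and 14.2 and 7.58, but these are not the values to be met with no change. The 17 arrays were kept for running together, across days too, which favours calls of one direction in advance. All days also share 1 dye term. Infarct RNA was in Cy3 on most kept arrays of days 3, 5 and 7, and in Cy5 on most of day 14. An error in that term moves days 3, 5 and 7 one way and day 14 the other. Days 3 and 14 lost no array and shared 211 higher and 137 lower genes, where independent lists would share 32.7 and 14.3. Part of the overlap may also come from shared controls, since it is unknown whether days shared sham animals. With the choice of arrays and shared controls open, the overlap alone cannot settle whether the days shared a response. The F test found 327 genes whose change differed among the days, 50 with a guessed swap pair of each day averaged, 0 with all 20 arrays as deposited (1518 at an unadjusted p under 0.05 in limma), and 341 or 1043 with the turned arrays. This count was 667 without day 3 array 1, 138 without day 3 array 5, 97 without day 14 array 4 and 134 without day 14 array 1. It was 147, 202, 211 and 170 without day 5 array 1, 2, 3 or 5, 172 without day 7 array 2 and 204 without day 14 array 2.

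From day 3 to day 5, 49 genes differed, 31 upwards and 18 downwards. With a guessed swap pair of each day averaged it was 1 gene. With the array number as a block it was 0 in limma (1563 at an unadjusted p under 0.05). Thbs4 (difference 1.18 ± 0.19), Clu (1.08 ± 0.22), Pdgfrl (0.86 ± 0.12), the small proteoglycan Dcn (0.86 ± 0.12) and Ecrg4 (0.86 ± 0.16) had the largest increases. Ptbp1 (-0.65 ± 0.12), the small heat shock protein Hspb7 (-0.64 ± 0.13), Dgat2 (-0.62 ± 0.11), St13 (-0.55 ± 0.09) and Stard3 (-0.54 ± 0.11) had the largest decreases. Their adjusted p ran from 0.00739 for Dcn and Pdgfrl to 0.0482 for Clu. The mean difference was 0.37 for collagens, with 0 of 16 members past the threshold (7 adjusted over the list alone), and 0.31 for matrix glycoproteins, with 3 of 33 (12 adjusted over the list alone). Both lists passed camera at the preset correlation but not with an estimated correlation (adjusted p = 0.254 and 0.256) or in fry (0.0566 and 0.0958). The count of genes fell to 4 without day 5 array 1, which alone held infarct RNA in Cy5 at day 5. It was 91 without day 3 array 1. Leaving out day 3 array 2, 4 or 5 gave 12, 10 and 9 genes, day 5 array 2, 3 or 5 gave 8, 8 and 15, day 7 array 2 gave 27, and day 14 array 1, 4 or 5 gave 25, 10 and 29. All 20 arrays gave 0 as deposited (1293 at an unadjusted p under 0.05 in limma), and 17 or 80 with the 3 turned.

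Few genes differed between the later neighbouring days. From day 5 to day 7, 3 genes passed in limma: the cartilage matrix protein Comp rose by 1.55 ± 0.23, Mfap4 by 0.87 ± 0.14, and the mitotic cyclin Ccnb2 fell by 0.83 ± 0.13, each with adjusted p = 0.0463. Each lost its call in several alternatives, including without day 7 array 2 (adjusted p = 0.366 for Comp, 0.177 for Mfap4 and 0.366 for Ccnb2), where 0 genes passed in limma (790 at an unadjusted p under 0.05). The cell cycle list differed between these days by a mean of -0.32 in camera at the preset correlation, with 1 of 38 members lower (16 adjusted over the list alone). It had adjusted p = 0.252 with an estimated correlation and 0.0566 in fry. From day 7 to day 14, 3 genes passed, all downwards: the protease inhibitors Serpinb1b (-1.11 ± 0.18, adjusted p = 0.045) and Serpinb1a (-1.08 ± 0.13, 0.00248), which are close paralogs that probes may not separate, and Krt18 (-0.54 ± 0.07, 0.00248). Serpinb1b lost its call without day 7 array 2 (0.317), day 14 array 1 (0.182) or day 14 array 4 (0.194), among others. No gene of this interval passed in limma after scaling of the arrays to a common spread, or with the array number as a block. From day 7 to day 14, 14 lists passed camera at the preset correlation, 12 of them downwards. Among them were collagens (mean -0.33), matrix glycoproteins (-0.37) and macrophage markers (-0.34). The mean for TCA cycle and oxidative phosphorylation was 0.19. In these 4 lists 0 members passed in limma. Adjusted over the list alone, 8, 12 and 6 were lower in the first 3 and 2 higher in the last. They had adjusted p = 0.256, 0.252, 0.317 and 0.256 with an estimated correlation, and in fry 0.112, 0.0681, 0.171 and 0.145. For the interval from day 5 to day 7, 0 genes also passed in limma without day 3 array 1, 3 or 5, day 5 array 2 or 5, or day 14 array 1, 4 or 5 (1568, 1492, 1547, 1375, 1389, 1506, 1461 and 1508 at an unadjusted p under 0.05). There was 1 gene without day 3 array 4 or day 14 array 3, there were 5 without day 3 array 2, day 5 array 3 or day 14 array 2, and 14 without day 7 array 1. For that from day 7 to day 14, the count was 16 without day 3 array 2, 10 without day 5 array 3, 17 without day 7 array 1, 13 without day 14 array 2 and 9 without day 14 array 5. All 20 arrays as deposited gave 0 in both (737 and 300 at an unadjusted p under 0.05 in limma), and the turned arrays 33 or 70 for the first and 110 or 251 for the second.

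From day 3 to day 14, 295 genes differed, 36 upwards and 259 downwards. Averaging a guessed swap pair of each day left 72. Gsn (1.42 ± 0.15), Klf4 (1.16 ± 0.27), Comp (0.94 ± 0.19), Clec3b (0.90 ± 0.19) and the protease Htra3 (0.86 ± 0.15) were higher at day 14, and Ccl2 (-1.64 ± 0.31), Adam8 (-1.27 ± 0.26), Mki67 (-1.26 ± 0.19), the actin-binding Cotl1 (-1.25 ± 0.20) and Sprr1a (-1.06 ± 0.15) lower. Of 38 cell cycle genes 16 fell by this test, with a list mean of -0.37 (28 lower adjusted over the list alone, fry adjusted p = 0.00692), and of 28 ribosomal protein genes 12 fell, with a mean of -0.39 (24 lower adjusted over the list alone, fry adjusted p = 0.00168). With an estimated correlation in camera these lists had adjusted p = 0.252 and 0.136. Read as not turned, the differences were 0.073 and 0.032 and did not pass (fry adjusted p = 0.992 for both). Macrophage markers differed by a mean of -0.36 with 3 of 27 lower (13 adjusted over the list alone), which passed camera only at the preset correlation (adjusted p = 0.324 with an estimated correlation). Calls of single genes were lost without day 14 array 4 for Klf4 (adjusted p = 0.145), Comp (0.0661), Adam8 (0.0777) and Ccl2 (0.0526), and without day 14 array 1 for Clec3b (0.0771). The count was 77 without day 14 array 4 and 589 without day 14 array 3; without day 3 array 1, 2 or 5 it was 574, 163 and 127, and without day 14 array 1 or 2 it was 134 and 147. All 20 arrays gave 0 as deposited (1693 at an unadjusted p under 0.05 in limma), and 139 or 375 with the 3 turned.

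The dye itself moved many genes. In limma 5115 genes had a dye effect at the threshold, 3885 with all 20 arrays as deposited, and 1041 or 6222 with the 3 arrays turned. Without the dye term in the fit, 1038 genes were called at day 7 and 229 at day 14; of the latter 49.8% were higher, against 58.7% with the term.

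**Figure D3:**
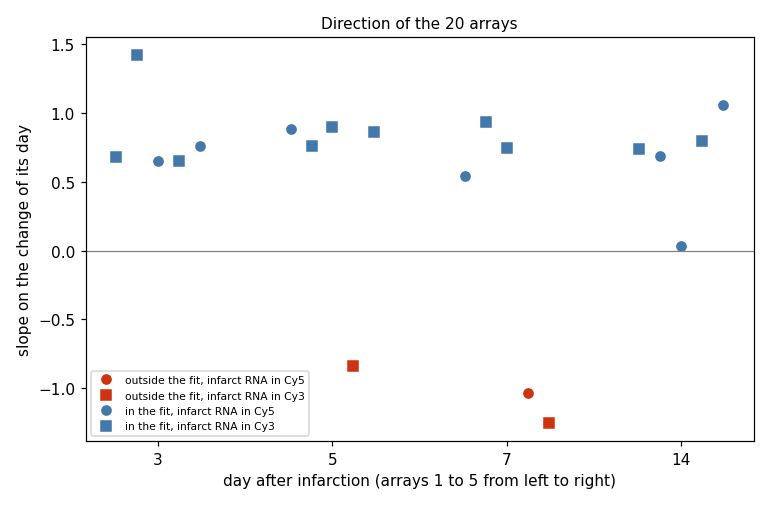
Slope of each array's log ratios on the change of its day estimated from the other arrays (vertical axis) against days after infarction (horizontal axis), with the dye of the infarct RNA by symbol. The 17 arrays of the fit lie from 0.0337 to 1.42 and the 3 arrays set aside from -1.25 to -0.839.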

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

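The tests of the 3 patterns weighed at the end of this part, and of gene lists between days, were chosen after the results were seen; the counts of other splits and the search for single deviating arrays had been planned.

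Single arrays stood far from the others of their day in 12 of 248 groups examined, where chance gives about 12.4. On day 3 array 2, dye-corrected values were high for Postn (3.49, others 2.68 to 2.87), Fstl1 (2.43, others 1.42 to 1.67) and Timp1 (1.75, others 0.35 to 0.64). On day 5 array 2, Atp2a2 was at -0.37 (others -0.74 to -0.69), Rpl6 at 0.70 (others 0.44 to 0.45) and the mean of the chemokines, cytokines and receptors at 0.045 (others 0.19 to 0.22). On day 5 array 1 Hlf was at -0.78 (others -0.45 to -0.41), and on day 5 array 5 the mean of the skeletal muscle markers was at 0.058 (others -0.018 to -0.0054). On day 14 array 3, the stress and fetal cardiomyocyte genes had a mean of 0.30 (others 0.68 to 0.83) and the renin-angiotensin, endothelin and natriuretic peptide genes one of 0.14 (others 0.29 to 0.34). On that array Acta1 was at 0.72 (others 1.3 to 1.5) and Meox1 at 0.37 (others 0.70 to 0.78).

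The change after infarction differed between time points, each by a test of the difference itself, for 327 genes in the F test. Assigning the 17 arrays to the days at random gave as many in 2 of 100 assignments, the real one included, with 358 as the highest other, a share under 0.05 if arrays are independent; the block gave 65 genes and the averaged swap pair 50. Between days 5 and 3, 49 genes differed, against 25 in the highest of 100 assignments and 1 as large, the real one. Chance is not excluded by this, since the assignments take arrays as independent and arrays of day 3 share animals. With a guessed swap pair averaged 1 gene passed, and with the array number as a block 0 in limma (1563 at an unadjusted p under 0.05). The 49 included Thbs4 (1.18), Clu (1.08), Pdgfrl (0.86), Dcn (0.86), Ecrg4 (0.86), Ptbp1 (-0.65), Hspb7 (-0.64), Dgat2 (-0.62), St13 (-0.55) and Stard3 (-0.54). Between days 7 and 5, 3 genes differed, Comp (1.55), Mfap4 (0.87) and Ccnb2 (-0.83); the highest other of 35 assignments gave 2, and 1 was as large, the real one. This margin of 1 gene also takes arrays as independent, and 0 genes passed in limma with the swap pair averaged, the block, no dye term or each probe alone (1067, 1338, 1036 and 2083 at an unadjusted p under 0.05). Between days 14 and 7, 3 genes differed, Serpinb1b (-1.11), Serpinb1a (-1.08) and Krt18 (-0.54). Here 3 of 56 assignments gave as many, with 36 as the highest other, and chance was not excluded.

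Between days 14 and 3, 295 genes differed, with 157 in the block and 72 with the averaged swap pair. Of 100 assignments, which also took arrays as independent, 2 gave as many, the real one included. The other one exchanged day 3 array 1 with day 14 array 3 and gave 1201 genes, several times the real count, which points to a structure among the arrays beyond the time point. The genes were Gsn (1.42), Klf4 (1.16), Comp (0.94), Clec3b (0.90), Htra3 (0.86), Ccl2 (-1.64), Adam8 (-1.27), Mki67 (-1.26), Cotl1 (-1.25) and Sprr1a (-1.06). The mean of the cell cycle list differed by -0.37 and that of the ribosomal proteins by -0.39. These 2 lists were the ones that passed among 120 list tests between days with fry, with 27 at an unadjusted p under 0.05. Camera gave 36 at the preset correlation (46 unadjusted) and 0 with an estimated correlation (19 unadjusted).

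For the changes against sham, other splits turned the sign of arrays. The 17 arrays had been kept for running together in sign, which favours the real choice in advance, so these splits decide nothing. On the mean of the 4 days 1 of 100 choices, the real one, gave as many genes (4821, highest other 2389), whereas all 20 arrays as deposited gave 0 in limma, with 3293 at an unadjusted p under 0.05. For gene lists with camera at the preset correlation it was 1 of 100 (77, highest other 72), and the median of the other choices was 41 calls. The dye effect gave 5115 genes, against 2422 in the highest other of 99 assignments, with 1 as large, the real one. Single days have too few splits for a share under 0.05: 1 of 16 at day 3 (3369, highest other 355), 1 of 8 at day 5 (2245, highest other 0), 1 of 4 at day 7 (1585, highest other 0) and 1 of 16 at day 14 (443, highest other 409).

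Signals also stood in data that the comparisons do not use. The 4357 spots with no single gene name held 478, 241, 165 and 41 past the threshold at days 3, 5, 7 and 14. The 3 arrays set aside had slopes on the change of their day of -0.839 (day 5 array 4), -1.04 (day 7 array 4) and -1.25 (day 7 array 5).

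The first pattern is that these 3 arrays run against the other 17. A sign error of the deposited columns alone would also reverse the dye effect, but its slope had the sign of the labelled dyes on 3 of 3 arrays (-0.335, 0.525 and -0.339), as on 17 of 17 others. The time point as a cause is argued against by the 7 arrays of days 5 and 7 that run with the other days. A candidate explanation is that infarct and sham RNA were exchanged in the record of those arrays, since their highest slope was -0.839 with the dye slope as labelled. Of the genes called at their day in the 17-array fit, 88.8% (day 5 array 4), 97.1% (day 7 array 4) and 95.3% (day 7 array 5) had the opposite sign. A real opposite response in those animals would have to reverse nearly the whole set of called genes. It predicts the same slopes and stays open, as untested.

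The second pattern is the clock genes at day 5, where Dbp and Per2 were low. Infarct and sham hearts may have been collected at different hours: the mean of Arntl, Clock and Npas2 was 0.19 and that of the other 12 clock genes -0.34, with an exact permutation p of 0.123 over 455 choices of 3 among 15 genes, which leaves this open. A single deviating array is also open. The highest adjusted p without 1 array was 0.131 (Per2 without array 1). Per2 then went from -1.02 to -0.77 and Dbp from -1.74 to -1.56 (adjusted p = 0.0661). Whichever array was left out, a share of 0.762 or more of the change remained, so the size of neither change rested on 1 array. Array 1 alone held infarct RNA in Cy5 at day 5, so a call lost without it cannot be laid to a deviation of that array. A first form of that test used the adjusted p alone and would have favoured the single array; the share was added after that outcome. The time point is open too, since the higher fry adjusted p of the list between day 5 and its neighbours was 0.272; after its outcome was seen, this replaced a test of Dbp on single arrays, in which 1 array of another day lay below those of day 5.

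The third pattern is the weak changes on day 14 array 3, whose slope on the change of its day was 0.0337, where the next lowest of the 17 arrays had 0.541. Exchange with day 3 array 1 is argued against: the cell cycle mean was 0.0521 on this array, below the lowest day 3 array (0.320), and 0.499 on day 3 array 1, above the highest other day 14 array (0.0730). List means cannot tell a smaller response in that sample from compressed ratios on that array. Both predict low means, as seen in 2 of 2 lists, collagens and stress genes, and the stress list had drawn attention to the array. Its slope on the dye effect was also the lowest of the 17, at 0.0672, which a smaller response alone does not predict. Day 7 array 1 had a dye slope nearly as low, 0.0765, with a slope of 0.541 on its day's change. A low dye slope thus does not decide between them. Of 685 genes called at day 14 without array 3, 37.7% had the opposite sign on it, against 0.76% to 23.8% on the other day 14 arrays. Its r with those arrays ran from -0.083 to 0.153. Neither a smaller response nor compressed ratios turns signs by itself. These values were not dye-corrected and hold noise too, so they do not settle what else acted on the array. For compression, 1 array with a lower spread had a slope of 0.5 or more; a first form of the test took 1 such array as excluding compression, and the bound was raised to 3 after that outcome.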

How the results depend on the processing

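The 3 readings of all 20 arrays were added after the data had been seen; the other alternatives were planned. All 20 arrays as deposited gave 1332 genes at day 3, 46 list calls, 3885 genes with a dye effect and 0 in limma for every other count: days 5, 7 and 14, the mean, the F test and the 4 differences between days (1395, 232, 711, 3293, 1518, 1293, 737, 300 and 1693 at an unadjusted p under 0.05, the differences in the order 5 against 3, 7 against 5, 14 against 7 and 14 against 3). With the 3 arrays turned and dyes as labelled, the counts that moved by over 1.5 times were day 7 (3329), day 14 (282), 5 against 3 (17), 7 against 5 (33), 14 against 7 (110), 14 against 3 (139) and the dye effect (1041). With dyes exchanged they were day 7 (4076), the F test (1043), 5 against 3 (80), 7 against 5 (70) and 14 against 7 (251). The cause was not tested. As deposited, 14 named values reversed: at day 7 Postn -0.055, Rbfox1 0.033, Ces1d 0.017, Acot1 0.055, Col1a1 -0.044, Timp1 -0.18, Mfap4 -0.036, Trem2 -0.046 and Gpnmb -0.15; for 7 against 5 Comp -0.051 and Mfap4 -0.25; for 14 against 7 Serpinb1b 0.25, Serpinb1a 0.25 and Krt18 0.32.

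Of 8237 alternative values of named genes, 7399 kept their direction and side of the threshold, 586 lost the call, 18 gained one and 234 reversed, 220 of these in the reading as not turned and 14 with all 20 arrays as deposited. Read as not turned, the table gave 1897 genes at day 3, 2 at day 5, 0 at day 7 (1913 at an unadjusted p under 0.05 in limma), 32 at day 14, 25 list calls, and 0 for the F test (827) and the 4 differences (842, 954, 474 and 477 in the above order); 442 of 551 values past the threshold, counted over all genes the naming rule takes, changed sign, 48 of them past it again. Without the dye term there were 1038 genes at day 7, 229 at day 14, 103 in the F test, 2 for 5 against 3, 0 for 7 against 5 (1036) and 112 for 14 against 3. Without centring, 14 against 7 gave 8. Scaling to a common spread gave 15 for 5 against 3, 0 for 14 against 7 (1191), 195 for 14 against 3 and 204 in the F test. Averaging a guessed swap pair at each day gave 816 genes at day 7 and 269 at day 14. It gave 50 in the F test, 1, 0 (1067), 5 and 72 for the differences and 2073 for the dye effect. Each probe alone gave 29 for 5 against 3 and 0 for 7 against 5 (2083), and the robust prior 5 for 14 against 7. Array weights gave 741 at day 14, 7 for 7 against 5 and 23 for 14 against 7. Separate fits gave 1562, 846 and 201 genes at days 3, 7 and 14, and 0 (1890), 5 and 58 for the last 3 differences. The estimated correlation gave 35 list calls. In all these the cause was not tested.

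The array numbers were tested for pairing. Over 22 pairs of one number on different days the mean r was -0.0221, against 0.0058 for other numbers, and 5 of 17 arrays correlated best with their own number, so no pairing was used. With the number as a block, 2789, 1361, 863 and 393 genes were called at days 3, 5, 7 and 14, 3399 on the mean, 65 in the F test, 0, 0, 0 and 157 for the differences (1563, 1338 and 983 at an unadjusted p under 0.05 in limma for the first 3), 3355 for the dye, and 79 gene list shifts.

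With each array left out in turn, counts ran from 1744 to 3504 at day 3, 1165 to 2418 at day 5, 760 to 1780 at day 7, 230 to 685 at day 14, 4031 to 4947 on the mean and 97 to 667 in the F test. The differences ran from 4 to 91 for 5 against 3, 0 to 14 for 7 against 5 (790 to 1932 at an unadjusted p under 0.05 in limma), 2 to 17 for 14 against 7 and 77 to 589 for 14 against 3, with 3768 to 5324 for the dye and 76 to 83 gene list shifts. A filter on missing or 0 values changed nothing, since there were 0 of each. Signal over background was not analysed here.

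Values of the named genes that reversed when the table was read as not turned follow; 49 others lost the call, and 7 kept it or stayed without one. At day 3 these were Postn -0.52, Nppa -0.19, Col8a1 -0.31, Nmrk2 -0.36, Ccn2 -0.25, Fstl1 -0.58, Tuba1a -0.34, Myh7 -0.081, Anxa2 -0.033 and Ccl2 -0.23. Then Ano10 0.11, Gsn 0.092, Cmya5 0.21, Pink1 0.073, Nr4a1 0.61, Hrc 0.073, Clec3b 0.023, Gstm1 0.028, Col3a1 -0.050 and Col1a1 -0.47. Then Timp1 -0.41, Col1a2 -0.39, Serpinh1 -0.12, Mmp14 -0.40, Ctss -0.0047, Uck2 -0.17, Des -0.91, Atp2a2 0.029, Sri -0.13 and Ldhb 0.32. Then Pgk1 -0.0059, Tnfrsf12a -0.43, Lgals3 -0.22, Trem2 -0.19, Isg15 -0.45, Bst2 -0.43, Pcna -0.027, Ccnd1 -0.25, Mki67 -0.33 and Vim -0.10. Then Krt18 -0.088, Hmox1 -0.091, Rpl12 -0.12 and Rpl3 -0.64. At day 5 these were Postn -0.50, Nppa -0.35, Myh7 -0.27, Col8a1 -0.35, Ccn2 -0.42, Nmrk2 -0.046, Ltbp2 -0.43, Nppb -0.21, Thbs4 -0.67 and Fstl1 -0.42. Then Dbp 0.22, Hrc 0.10, Gsn 0.28, Ces1d 0.15, Shld1 0.054, Gpcpd1 0.45, Per2 0.073, Col3a1 -0.44, Col1a1 -0.63 and Timp1 -0.27. Then Loxl1 -0.26, Ctss -0.43, Mmp14 -0.53, Ckm 0.040, Tnni3 0.19, Pln 0.10, Eci1 0.048, Sdha 0.12, Osmr -0.36 and Trem2 -0.41. Then Ms4a7 -0.20, Mpeg1 -0.44, Adgre1 -0.12, C1qb -0.37, C1qa -0.34, Ccnb2 -0.34, Cdc20 -0.14, Meox1 -0.29, Cilp -0.35 and Krt18 -0.28. Then Tgfb3 -0.43, Tgfbr2 -0.37, Nppc -0.032, Hlf 0.10, Arntl -0.052, Sfrp1 -0.33, Frzb -0.12 and Rpl6 -0.14. At day 7 these were Myh7 -0.24, Nppa -0.59, Col8a1 -0.33, Postn -0.24, Ltbp2 -0.70, Ccn2 -0.42, Clu -0.31, Ankrd1 -0.20, Nmrk2 -0.32 and Nppb -0.22. Then Ift81 0.27, Rbfox1 0.13, Rgcc 0.037, Etfa 0.14, Acot1 0.15, Col3a1 -0.49, Col1a1 -0.59, Timp1 -0.33, Acta1 -0.35 and Mfap4 -0.67. Then Tnni3 0.14, Pln 0.17, Atp2a2 0.0050, Ech1 0.0092, Uqcrfs1 0.10, Trem2 -0.11, Lgals3 -0.35, Gpnmb -0.34, Prtn3 -0.39 and Kif22 -0.14. Then Top2a -0.28, Meox1 -0.25, Cilp -0.42, Mybpc2 -0.23, Krt18 -0.14, Tgfb3 -0.53, Gpx3 -0.49, Hspd1 0.17, Sfrp1 -0.65 and Sfrp2 -0.87. At day 14 these were Myh7 -0.11, Nppa -0.42, Postn -0.40, Col8a1 -0.29, Ccn2 -0.47, Fstl1 -0.50, Nppb -0.56, Ltbp2 -0.33, Col1a2 -0.24 and Col3a1 -0.28. Then Ift81 0.19, Rbfox1 0.026, Hrc 0.019, Acaa2 0.081, Ces1d 0.18, Aldh6a1 0.00031, Col1a1 -0.20, Timp1 -0.18, Acta1 -0.15 and Mfap4 -0.34. Then Loxl1 -0.13, Tnni3 0.15, Pln 0.10, Cox7a1 0.022, Tnfrsf12a -0.38, Lgals3 -0.11, Trem2 -0.19, Cilp -0.25, Meox1 -0.29 and Mybpc2 -0.10. Then Myl1 -0.63, Krt18 -0.15, Tgfb3 -0.18, Nppc -0.16 and Rpl3 -0.34. On the mean of the 4 days these were Nppa -0.39, Postn -0.42, Myh7 -0.17, Col8a1 -0.32, Ccn2 -0.39, Nmrk2 -0.27, Nppb -0.24, Fstl1 -0.49, Ltbp2 -0.42 and Ankrd1 -0.19. Then Ift81 0.14, Rbfox1 0.0054, Dbp 0.11, Ces1d 0.13, Pink1 0.10, Cmya5 0.10, Col3a1 -0.31, Col1a1 -0.47, Timp1 -0.30 and Acta1 -0.054. Then Ldhb 0.18, Pfkp -0.21, Slc2a4 0.0086, Blnk -0.21, H2-DMb1 -0.13, Icam2 -0.18, Aqp1 0.035, Cnn1 -0.018, Pdgfrb -0.086 and Mybpc2 -0.15. Then Cidea -0.082, Krt18 -0.17 and Gpx3 -0.38. Day 5 against day 3 these were Thbs4 -0.50, Clu -0.28, Pdgfrl -0.35, Dcn -0.37, Ecrg4 -0.17, Ptbp1 0.36, Hspb7 0.44, Dgat2 0.14, St13 0.23 and Stard3 0.18. Day 7 against day 5 these were Comp -1.25, Mfap4 -0.56 and Ccnb2 0.22. Day 14 against day 7 these were Serpinb1b 0.059. Day 14 against day 3 these were Klf4 -0.24, Comp -0.23, Htra3 -0.19, Adam8 0.16, Mki67 0.12 and Sprr1a 0.10. The reading itself swaps the roles of dye and infarct. In it, calls were 993 higher and 904 lower at day 3, and 1925 higher and 2516 lower on the mean.

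Means of the gene lists with the table read as not turned, at days 3, 5, 7 and 14, were those of collagens (-0.16, -0.30, -0.36 and -0.16), matrix glycoproteins and matricellular proteins (-0.15, -0.23, -0.33 and -0.16) and matrix proteases and inhibitors (-0.081, -0.13, -0.11 and -0.10). Then came stress and fetal cardiomyocyte genes (0.057, -0.076, -0.18 and -0.12), adult contractile genes (-0.084, -0.03, -0.072 and -0.023) and ion channels and calcium handling (0.0048, -0.034, 0.02 and -0.0096). Next came fatty acid oxidation (0.0031, -0.06, 0.023 and -0.066), TCA cycle and oxidative phosphorylation (-0.078, -0.02, 0.038 and -0.032) and glucose uptake and glycolysis (-0.065, -0.035, -0.039 and -0.062). Then came chemokines, cytokines and their receptors (-0.073, -0.068, -0.055 and -0.11), macrophage and monocyte markers (-0.16, -0.17, -0.15 and -0.18) and neutrophil markers (-0.087, -0.038, -0.11 and -0.087). Next came lymphocyte markers (0.062, 0.0093, -0.0069 and 0.023), MHC class II (-0.022, -0.061, -0.12 and -0.087) and complement (-0.023, -0.11, -0.13 and -0.12). Then came interferon response (-0.11, -0.077, -0.094 and -0.15), cell cycle (-0.13, -0.072, -0.019 and -0.058) and fibroblast and myofibroblast markers (-0.11, -0.15, -0.17 and -0.14). Next came endothelial markers (-0.10, -0.10, -0.13 and -0.075), smooth muscle and pericyte markers (0.013, -0.051, -0.081 and 0.015) and skeletal muscle markers (0.016, -0.028, -0.084 and -0.045). Then came adipocyte markers (0.061, 0.045, -0.0013 and 0.037), red cell markers (0.048, 0.11, -0.18 and -0.061) and mesothelial markers (0.029, -0.056, 0.013 and -0.013). Next came TGF-beta and BMP signalling (-0.081, -0.092, -0.074 and -0.052), renin-angiotensin, endothelin and natriuretic peptide system (-0.0011, -0.068, -0.11 and -0.082) and heat shock, hypoxia and oxidative stress (-0.079, -0.047, -0.026 and -0.11). Then came circadian clock (0.013, 0.029, 0.031 and 0.0068), Wnt pathway (0.023, -0.038, -0.093 and 0.0028) and ribosomal proteins (-0.19, -0.085, 0.014 and -0.16). In limma 0 members of any list passed at days 5, 7 and 14 in this reading. At day 3, 0 collagens, 3 matrix glycoproteins, 3 TCA cycle and oxidative phosphorylation genes, 1 cell cycle gene and 6 ribosomal protein genes were lower (0, 3, 3, 1 and 8 adjusted over the list alone), with 0 higher. Of the fatty acid oxidation genes 2 were higher and 2 lower, also adjusted over the list alone. Adjusted over the list alone, 4 and 6 collagens were lower at days 5 and 7. Of the 150 list tests, 25 passed camera at the preset correlation, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 9 in fry (35 unadjusted). Of the calls in the reading used, those whose mean changed sign were 64 of 77, 28 of 35 and 75 of 93 in these 3 tests. Between days, 4 of 120 tests passed camera at the preset correlation, 0 with an estimated correlation (1 unadjusted) and 0 in fry (2 unadjusted).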
